A study of Mus musculus with 8 samples.

How the data were processed

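The series measured messenger RNA levels in the tibialis anterior, a predominantly fast-fibre muscle of the lower hind leg, of male C57BL/6 mice aged 8 weeks. Per the labels' protocols, the left sciatic nerve was transected and the muscles of both legs were taken 7 days later. The contralateral muscle of an operated animal, not that of a sham-operated one, was the innervated control. Total RNA was extracted with TRIzol, and 50 ng per sample was amplified with a whole-transcript single-primer isothermal kit, fragmented to an average of 85 bases and labelled with biotin for an oligonucleotide array. Each of the 8 samples was 1 array, 4 innervated and 4 denervated.

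The deposited table holds log2 intensities, 1 per probe set and array, made by the authors with GCOS and RMA, which corrects background, normalizes between arrays and summarises the probes of a set, per the submitters' processing notes. Those notes name the genome build mm9; program versions, the probe set definition and any filter are not given in the sources used here. The values ran from 1.67 to 13.1 with array medians between 5.84 and 6.00, which is the range of a log2 scale. The 8 distributions were not identical, so the final table was not quantile-normalized at the level of the probe sets. The table has no detection p-values, so no probe set could be called absent, and the number of arrays limits the precision. All 8 columns of the table were used.

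Of 16755 probe sets, 14996 had exactly 1 gene symbol in the platform annotation, 1019 had several and 740 had none. Gene names were checked against the RefSeq gene table of GRCm38.p6 through their Entrez Gene IDs. No symbol changed, and the IDs of 14805 tested genes were found there. That assembly differs from the build in the processing notes, so no coordinates are given. For the 135 genes with more than 1 probe set, the one with the highest mean over all arrays was taken, which left 14860 genes. Trim63 and Myh4, which were among the genes set in advance, are not analysed here.

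The main test was a linear model with group and replicate number as terms, fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation at default settings, two-sided, and Benjamini-Hochberg adjustment over all 14860 genes; a gene passed at an adjusted p under 0.05. The model has 3 residual and 4.57 prior degrees of freedom. The replicate number was kept as a block because the submitters' design normalizes each denervated muscle to the contralateral one. The labels do not say that equal numbers mark 1 animal. After subtraction of the group means, same-numbered arrays correlated at 0.23 for number 1, -0.03 for number 2, 0.45 for number 3 and 0.35 for number 4 across genes, so the arrays of number 2 showed no sign of pairing. Innervated 1 and 2 and denervated 2 correlated best with another number than their own. Results without the block are therefore printed where they change the call of a named gene or move a count of list members by over 1.5 times. Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure the spread between these samples.

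A total of 29 gene lists, 8 of them cell type markers, were fixed before the data were examined, as were the design, the alternatives and the rule for naming genes. Of 623 listed members, 498 were measured. The lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 29 lists. With the correlation estimated from the data, camera rests on the 3 residual degrees of freedom, and no list passed. Fry, which asks whether a list's genes move on balance one way, was a further alternative. The genes named are the 12 with the largest rise and the 12 with the largest fall among those past the threshold and changed the same way in all 4 pairs, 14 genes set in advance, and per list the 2 called members with the largest change in the list's main direction and the 1 with the largest in the other. Other members are named to complete a count or because an alternative changed their call, and were chosen after their values were seen.

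The fit was tested on simulated data made from the real means and moderated spreads of the 14860 genes, with noise drawn independently for each gene. Of 60 genes changed by 1 on the log2 scale 59 were recovered, of 60 changed by 2 all 60, and of 80 changed by 0.5 only 18, with 4 unchanged genes among 141 calls. None of 20 unchanged lists passed camera, but independent noise holds no correlation between genes. In the data that correlation was estimated at up to 0.83, for proteasome subunits. The simulation therefore does not test camera's p-values for lists of correlated genes. The alternatives tried were no replicate block, the block as a random effect, quantile, median and cyclic loess normalization, removal of the dimmest 25% or 50% of genes, the mean of a gene's probe sets, every probe set on its own, trended and robust moderation, array weights, and each replicate number left out. Cyclic loess and a polyamine list without Smox were added after seeing the data.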

Results

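Gene expression was compared between the denervated tibialis anterior, 7 days after transection of the sciatic nerve, and the contralateral innervated muscle, with 4 arrays per group. The question was how loss of the nerve changes skeletal muscle mRNA levels. Values are log2 intensities, and a change is the denervated minus the innervated value with its SE from limma over 4 pairs. The arrays had medians between 5.84 and 6.00. The arrays of replicate 3 stood apart, with an SD over probe sets of 1.36 in the innervated and 1.25 in the denervated muscle, against 1.45 to 1.56 on the other 6 arrays. Denervated replicate 3 correlated with the other denervated arrays at 0.927 to 0.930 over probe sets, whereas the closest denervated pair reached 0.986.

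Denervation changed 1255 of 14860 genes, of which 529 rose and 726 fell, and every one of them moved in the same direction in all 4 pairs. At least 2-fold changes were found for 319 genes, 137 higher and 182 lower. The largest rise was that of Krt18, an intermediate filament keratin, which increased 10.8-fold from 6.95 ± 0.47 to 10.38 ± 0.43 (log2 mean ± SD, n = 4; limma adjusted p = 0.000232). It was followed by the stretch-responsive ankyrin repeat gene Ankrd1 (10.1-fold), the ectodysplasin receptor Eda2r (8.19-fold), the prostaglandin-degrading enzyme Hpgd (7.97-fold), the acetylcholine receptor subunit Chrna1 (7.44-fold), the metallothionein Mt2 (7.36-fold), the calgranulin S100a8 (7.32-fold) and the cell adhesion glycoprotein Emb (6.97-fold). Cdkn1a, Sln, Cpne2 and Gadd45a completed the 12 largest rises, at 6.36-, 6.31-, 5.86- and 5.78-fold. The rise of S100a8 differed between pairs, at 0.36, 3.92, 4.20 and 3.01, and its mean was 3.71 without replicate 1 against 2.87, above the 3.46 of Krt18 and the 3.70 of Ankrd1 there; Mt2 rose by 3.48 with array weights against 2.88. The largest fall was that of the hydrolase gene Cmbl, from 8.44 ± 0.23 to 4.84 ± 0.17, or 12.2-fold (adjusted p = 7.12e-05). Smox, which encodes spermine oxidase, fell 11.1-fold, the anoctamin Ano5 10.5-fold, Ostn, which encodes the secreted peptide musclin, 9.89-fold, and Dhrs7c, a reductase of the sarcoplasmic reticulum, 9.73-fold. Fbp2, the muscle fructose-bisphosphatase, fell 8.04-fold, Mlf1 7.39-fold, Mgst3 6.29-fold, the muscle ribosomal protein gene Rpl3l 6.15-fold, the muscle enolase Eno3 5.82-fold, the kinase gene Map2k6 5.72-fold and Asb12 5.63-fold. The denervated means of Cmbl (4.84) and Ostn (4.71) and the innervated mean of S100a8 (4.86) lay below the lower quartile of every array (4.98 to 5.36), and the denervated means of Asb12 and Mlf1 within that range. No detection values exist to tell such levels from background, so these folds and their ranks are of intensity and may understate the change in mRNA. Without the block 800 genes passed, 785 of them shared with the 1255, and S100a8 did not (adjusted p = 0.0631), nor did it without replicates 2 and 4 (0.0895 and 0.0666). The count was 1643 without replicate 3, with 862 higher and 781 lower, and fell to 347, 651 and 486 without replicates 1, 2 and 4.

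**Figure D1:**
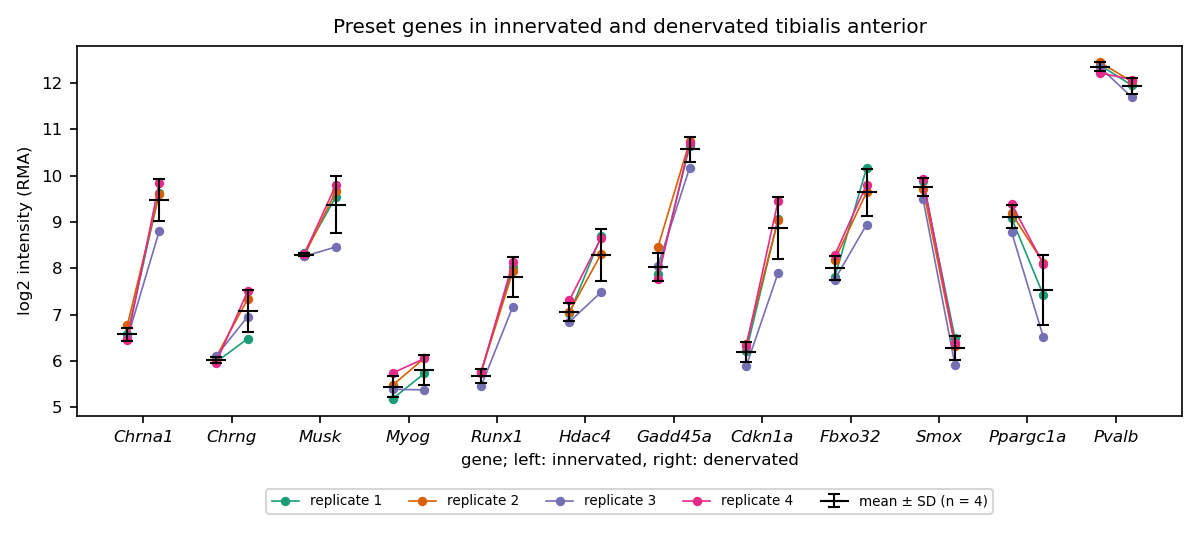
Log2 intensity (vertical axis) of 12 genes set in advance, in innervated (left) and denervated (right) muscle; points are arrays, coloured lines join arrays of the same replicate number, and black marks are the mean ± SD of 4 arrays. Chrna1 rose from 6.58 to 9.47 and Smox fell from 9.75 to 6.28, while Myog and Pvalb did not pass the test.

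Genes of the neuromuscular junction changed in both directions. Of 15 measured members 6 rose, namely Chrna1, Ncam1, Chrnd, Chrnb1, Musk and Chrng, and 1 fell, Ache, which encodes acetylcholinesterase. Chrna1, the acetylcholine receptor alpha subunit, rose by 2.89 (SE 0.17, adjusted p = 0.000232), and the neural cell adhesion molecule Ncam1 by 1.39 (SE 0.19, adjusted p = 0.00549). The receptor subunits Chrnd and Chrnb1 rose by 1.34 and 1.24, the receptor-clustering kinase Musk by 1.08 (SE 0.21) and the fetal subunit Chrng by 1.05 (SE 0.17), the last from a dim baseline of 6.03 ± 0.07 near the array median. Ache changed by -0.92 (SE 0.12, adjusted p = 0.00527). The adult subunit Chrne had a change of -0.55 and Rapsn of 0.04, neither past the threshold over all genes. Chrne passed without the block (adjusted p = 0.0495), as it did with the block as a random effect, the dimmest 25% left out, trended and robust moderation, array weights and cyclic loess (0.0206 to 0.0449), where 2 members fell. The list passed camera (adjusted p = 0.00238), with an adjusted p = 0.39 with an estimated correlation. Adjusted over the list alone, 6 rose and 2 fell. Without replicate 1 or replicate 2 only 3 members rose; Chrnd missed the threshold in both (0.0818 and 0.0554) and Chrnb1 in the first (0.0515). Musk missed the threshold without replicates 1, 2 and 4 (adjusted p of 0.121, 0.0916 and 0.0868), Chrng without replicate 2 (0.0559) and Ache without replicate 1 (0.0509).

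Among myogenic and denervation-responsive regulators, 6 of 19 measured genes rose and 1 fell. Gadd45a, a growth arrest gene, rose 5.78-fold from 8.04 ± 0.30 to 10.57 ± 0.27, and the transcription factor Runx1 rose 4.4-fold (adjusted p = 0.000297 for each). Myf6, a muscle regulatory factor, rose by 1.88, Id2 by 1.51, Hdac4, a class II histone deacetylase, by 1.23 (SE 0.17, adjusted p = 0.00549) and Myod1 by 0.49. Hdac9 changed by -0.96 (SE 0.20, adjusted p = 0.0299). Myog, the gene of myogenin, was dim, at 5.45 ± 0.23 and 5.81 ± 0.32, and its change of 0.36 (SE 0.13) missed the threshold (adjusted p = 0.156), though it passed without replicate 3 (adjusted p = 0.0357) and with array weights (0.0376). The list passed camera as higher (adjusted p = 0.0193), with an adjusted p = 0.286 with an estimated correlation, while its median was -0.06 and its mean 0.40. The median was above 0 after quantile (0.14) and cyclic loess (0.11) normalization, with the dimmest 25% or 50% left out (0.23 and 0.49), with array weights (0.003) and without replicates 2 and 3 (0.09 and 0.04). Adjusted over the list alone, 8 rose and 2 fell. Without replicate 2 the list missed the threshold (adjusted p = 0.0564). Without replicate 3, 9 members rose and 2 fell, 2 also fell with the random block and after quantile, median and cyclic loess normalization, and 3 with array weights. Hdac9 missed the threshold without replicates 1 and 4 (0.121 and 0.115). Myod1 missed it after median centring (0.0517) and without replicates 1, 2 and 4 (0.178, 0.149 and 0.0966).

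Of 19 measured ubiquitin ligases and FoxO-linked atrophy genes 8 rose and none fell. They were Mt2, Cdkn1a, Gadd45a, Fbxo32, Fbxo30, Mdm2, Mt1 and Pdk4, so that 3 of the 8, Fbxo32, Fbxo30 and Mdm2, encode ubiquitin ligase components. Fbxo32, the muscle ubiquitin ligase atrogin-1, rose 3.1-fold (log2 change 1.63, SE 0.19, adjusted p = 0.00272), and Mt2 rose by 2.88 (SE 0.42). The list's camera adjusted p was 9.11e-05, and its adjusted p = 0.286 with an estimated correlation. Over the list alone 9 rose and 2 fell, and without replicate 1, where Mt2 missed the threshold (0.0567), only 5 rose over all genes. Pdk4 missed the threshold without the block (0.236), with the random block (0.0717) and without replicates 1 and 2 (0.0917 and 0.0673), and Mt1 without replicates 1 and 4 (0.119 and 0.102). Of 26 proteasome subunits 11 rose and none fell, with a median change of 0.57 ± 0.32 (SD of the 4 pair medians). The pair medians were 0.68, 0.65 and 0.76 in pairs 1, 2 and 4 and 0.05 in pair 3, whose arrays stood apart. Psmb1 rose by 0.86 (SE 0.14) and Psmb4 by 0.74 (SE 0.14), the latter with an adjusted p = 0.0704 without the block. The proteasome list passed camera (adjusted p = 3.88e-12), with an adjusted p = 0.328 with an estimated correlation, which was estimated at 0.83. Over the list alone 22 rose and 1 fell. Fry did not call the list (adjusted p = 0.0681). The proteasome count of 11 was 18 after quantile normalization, 23 after cyclic loess, 18 with the dimmest 50% of genes left out, 22 with array weights, where 1 fell, and 22 without replicate 3. It was 5 without the block and 0, 1 and 0 without replicates 1, 2 and 4, with Psmb4 missing the threshold without replicate 2 too (0.0586).

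Of 26 autophagy and lysosome genes 8 rose and 1, the kinase gene Ulk2, fell (change -0.54, SE 0.11, adjusted p = 0.0226). The cathepsin gene Ctss rose by 1.55 (SE 0.23) and Ctsl by 0.96 (SE 0.11, adjusted p = 0.00229), and the others were Sqstm1, Map1lc3a, Ctsd, Gabarapl1, Nbr1 and Ctsz. Ctss is abundant in leukocytes, whose markers had a median change of 0.52 in the same samples. The list's camera adjusted p was 0.000303, and its adjusted p = 0.369 with an estimated correlation; over the list alone 9 rose and 1 fell. Without the block 3 rose, with Sqstm1, Ctsd, Gabarapl1, Nbr1 and Ctsz between 0.0628 and 0.151 in adjusted p. The count was 2, 3 and 2 without replicates 1, 2 and 4, where Ulk2 missed the threshold too (0.110, 0.0542 and 0.112). After median centring Ctsz and Nbr1 missed it (0.0633 and 0.0524). Of 20 p53 targets and arrest genes 6 rose, namely Eda2r, Cdkn1a, Gadd45a, Rb1, Plk2 and Mdm2, of which 3 are shared with the atrophy list. Eda2r rose 8.19-fold and the cyclin-dependent kinase inhibitor Cdkn1a 6.36-fold (6.20 ± 0.22 against 8.87 ± 0.67, adjusted p = 0.000423), while Ccng1 changed by -0.57 (SE 0.11, adjusted p = 0.0195). Ccng1 missed the threshold after quantile normalization (change -0.33, adjusted p = 0.0772) and without replicates 1, 2 and 4 (0.112, 0.0575 and 0.0725), and Plk2 without the block (0.0766) and without replicate 1 (0.110), while with array weights 2 members fell. The p53 list's camera adjusted p was 0.000229, and its adjusted p = 0.217 with an estimated correlation; over the list alone 9 rose and 2 fell. Of 8 polyamine genes only Smox was called, falling from 9.75 ± 0.20 to 6.28 ± 0.25 (SE of the change 0.10, adjusted p = 2.17e-05). The polyamine list passed as lower (adjusted p = 0.00944), with an adjusted p = 0.217 with an estimated correlation and an adjusted p = 0.15 once Smox was left out; over the list alone 2 fell, as did 2 over all genes with array weights or with the dimmest 50% left out.

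Genes of energy metabolism fell broadly. All 19 measured genes of the citrate cycle list fell, with a median of -0.81 ± 0.18 (SD of the 4 pair medians). That list also holds pyruvate dehydrogenase complex genes and the aminotransferase gene Got1, which are not part of the cycle itself. The largest falls were those of Idh3a, a subunit of isocitrate dehydrogenase, at -1.87 (SE 0.22, adjusted p = 0.00304) and Got1 at -1.46 (SE 0.12). Of 40 oxidative phosphorylation genes 33 fell and none rose, with a median of -0.71 ± 0.15; Sdhb changed by -1.23 (SE 0.14, adjusted p = 0.0031) and Ndufs1 by -1.12 (SE 0.15). Of 19 glycolysis and glycogen genes 15 fell and none rose, with a median of -1.52 ± 0.31, led by Fbp2 at -3.01 (SE 0.23, adjusted p = 0.000558) and Eno3 at -2.54 (SE 0.22, adjusted p = 0.00098). Of 19 fatty acid genes 12 fell and none rose, with a median of -0.64 ± 0.11; Acadm, the medium-chain acyl-CoA dehydrogenase, changed by -1.62 (SE 0.14) and Acaa2 by -1.48 (SE 0.13). Among 15 regulators of oxidative metabolism 5 fell, namely Ppargc1a, Prkaa2, Nr4a1, Vegfa and Ppara. Ppargc1a, the coactivator PGC-1 alpha, fell 2.98-fold (9.11 ± 0.25 against 7.54 ± 0.75, adjusted p = 0.00358), and Prkaa2, a catalytic subunit of AMP-activated protein kinase, changed by -1.14 (SE 0.19), with an adjusted p = 0.0575 without the block and 0.0583 without replicate 1. Ppara missed the threshold without replicates 1, 2 and 4 (0.110, 0.129 and 0.164).

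Camera gave adjusted p-values of 3.25e-18 for the citrate cycle, 1.64e-26 for oxidative phosphorylation, 6.93e-16 for glycolysis, 8.63e-11 for fatty acid oxidation and 0.000303 for the regulators. The first 4 lists had an adjusted p = 0.217 with an estimated correlation, and the regulators an adjusted p = 0.281. Adjusted over each list alone, 19, 39, 16, 13 and 6 members fell in the same order, and 1 gene of the glycolysis and glycogen list rose. That gene, the glycogen branching enzyme Gbe1, also passed over all genes after quantile and cyclic loess normalization, with the dimmest 25% or 50% left out, with array weights and without replicate 3 (adjusted p of 0.00684 to 0.0347). Sdha and Sdhb are in both of the first 2 lists. Without the block 12 citrate cycle, 17 oxidative phosphorylation and 6 fatty acid genes fell. Without replicate 1 the counts were 7, 9 and 5 and the regulators numbered 3, without replicate 4 they were 9, 17 and 5, and without replicate 2 oxidative phosphorylation counted 21; the medians of these 3 lists under these settings stayed between -0.60 and -0.91.

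Of 14 measured fast-fibre genes 6 fell and none rose, led by the Z-disc gene Myoz1 at -1.81 (SE 0.14, adjusted p = 0.000558) and the M-band gene Myom2 at -1.62 (SE 0.18, adjusted p = 0.00222). The listed myosin heavy chain genes Myh1, Myh2 and Myh4 were not measured. Pvalb, the calcium buffer parvalbumin, went from 12.35 ± 0.10 to 11.94 ± 0.17, a change of -0.41 that missed the threshold (adjusted p = 0.0813) but passed with the block as a random effect (adjusted p = 0.0339) and with the dimmest 25% or 50% of genes left out (0.0499 and 0.0354). Its change was -0.20 after quantile and -0.18 after cyclic loess normalization. The fast list's camera adjusted p was 9.14e-10, and its adjusted p = 0.217 with an estimated correlation; over the list alone 10 fell, as did 10 over all genes with the dimmest 50% left out, and without replicate 1 or 4 the count was 3 or 4. Of 10 measured slow-fibre genes, which lack the listed Myh7 and Myh7b, 1 rose and 2 fell. Sln, which encodes the calcium pump regulator sarcolipin, rose 6.31-fold (5.47 ± 0.34 against 8.13 ± 0.33, adjusted p = 0.00074). Myl2 changed by -1.25 (SE 0.28, adjusted p = 0.0372), and Pln by -0.57 (SE 0.12, adjusted p = 0.0253). Myl2 missed the threshold without the block (0.127), after quantile (0.0823), median (0.0569) and cyclic loess (0.0549) normalization, and without replicates 1, 3 and 4 (0.0968, 0.0563 and 0.102). Pln missed it without replicates 1, 2 and 4 (0.0994, 0.0546 and 0.143). The slow list did not pass (adjusted p = 0.847); its mean was 0.05, and over the list alone 2 rose and 2 fell. Its median was -0.13 and turned to 0.12 and 0.03 without replicates 1 and 4, with -0.26 and -0.39 without replicates 2 and 3, -0.34 with array weights and -0.04 after quantile and cyclic loess normalization.

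Of 12 measured developmental muscle genes 4 rose and none fell, namely Ankrd1, Tnnt2, H19 and Peg3. The listed myosin heavy chain genes Myh3 and Myh8 were not measured, nor were Actc1 and Myl4. Ankrd1 rose by 3.34 (SE 0.25, adjusted p = 0.000558) and Tnnt2, the cardiac and embryonic troponin T, 4.13-fold (adjusted p = 0.000687). The list's camera adjusted p was 0.00143, and its adjusted p = 0.325 with an estimated correlation; over the list alone 5 rose. Of 21 excitation-contraction coupling and ion channel genes 12 fell and 2 rose. Mstn, which encodes the growth inhibitor myostatin and had been put in this list, fell 2.98-fold (adjusted p = 0.0137), and the potassium channel Kcna7 fell 2.74-fold (adjusted p = 0.00112). Kcnn3, a small-conductance calcium-activated potassium channel, rose 3.79-fold (5.75 ± 0.07 against 7.67 ± 0.62, adjusted p = 0.0031), and the calcium channel subunit Cacng1 rose by 1.21. The list's camera adjusted p was 2.37e-06, and its adjusted p = 0.286 with an estimated correlation; over the list alone 2 rose and 13 fell, and 4, 8 and 7 fell without replicates 1, 2 and 4, with Mstn at 0.0662 without replicate 1. Without the block 1 rose and 9 fell, with Cacng1 at 0.116, and Peg3 of the developmental list was at 0.0905. Without replicates 1, 2 and 4 Cacng1 (0.0856, 0.0586 and 0.0577) and Peg3 (0.0946, 0.0643 and 0.073) missed the threshold as well.

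Of 22 TGF-beta and BMP genes the receptor gene Tgfbr1 (change 1.44, SE 0.22) and the myostatin antagonist Fst (0.73, SE 0.14) rose and Mstn fell, and the list did not pass (adjusted p = 0.16; over the list alone 5 rose and 2 fell). Over all genes 5 rose and 2 fell without replicate 3, 6 and 2 with array weights and 4 and 1 with the dimmest 50% left out, and 2 also fell with the random block, the dimmest 25% left out and cyclic loess. Of 24 proliferation genes Mki67 (0.78) and Mcm6 (0.51) rose and the mitotic kinase Aurka (-0.73, SE 0.12) fell. Mki67 and Mcm6 missed the threshold without the block (0.383 and 0.0736) and after quantile normalization (0.0785 and 0.0517), Mki67 also with the random block (0.162) and Mcm6 without replicate 3 (0.0629). The list did not pass (adjusted p = 0.172; over the list alone 2 rose and 1 fell). Of 19 ATF4 and endoplasmic reticulum stress genes only Chac1 was called by limma over all genes (-0.53, SE 0.13, adjusted p = 0.0413). It was not called without the block (0.213), with the random block (0.0713) or after quantile (0.0628) or cyclic loess (0.0591) normalization. The list did not pass (adjusted p = 0.632; over the list alone 2 rose and 2 fell). Without replicate 3, 2 members rose, Atf3 and Xbp1, and 2 fell, Atf4 and Chac1. In the same order the counts were 2 and 0 with the random block, 3 and 0 after cyclic loess, 1 and 2 with the dimmest 25% and 3 and 2 with the dimmest 50% left out, 1 and 1 with trended and robust moderation, and 3 and 3 with array weights. Without replicate 1 no member of these 3 lists passed, and Fst, Mki67, Mcm6 and Chac1 missed the threshold without replicates 2 and 4 too (0.0652 to 0.203), as did Aurka without replicate 4 (0.0705). Of 12 clock genes Bhlhe41 (-1.18, SE 0.11) and Hlf (-0.89, SE 0.13) fell, as did both over the list alone. The clock list passed as lower (adjusted p = 0.0232), with an adjusted p = 0.369 with an estimated correlation and 0.105 without replicate 3, and Hlf missed the threshold without replicate 1 (0.0565), while with array weights 1 member rose. Of 11 measured ribosomal protein genes, out of 40 listed, Rpl23 (0.71, SE 0.16) and Rpl22 (0.54, SE 0.10) rose, and probes of such genes can bind processed pseudogene copies. The ribosomal list's adjusted p was 0.00203, and its adjusted p = 0.286 with an estimated correlation; over the list alone 6 rose. Rpl22 had an adjusted p = 0.0509 without the block and Rpl23 of 0.0623 after median centring. The count was 4 with array weights or with the dimmest 50% left out, and no member was called without replicate 1, 2 or 4.

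Markers of other cell types moved apart. Of 21 macrophage and leukocyte markers 9 rose and none fell, with a median of 0.52 ± 0.17 (SD of the 4 pair medians); the signalling adaptor Tyrobp rose 2.94-fold (7.81 ± 0.17 against 9.37 ± 0.30, adjusted p = 0.000765) and the galectin Lgals3 2.35-fold (adjusted p = 0.00148). Of 15 endothelial markers 4 fell and none rose, with a median of -0.21 ± 0.04: the receptor genes Kdr (-0.77, SE 0.13) and Flt1 (-0.58), and Emcn (-0.72, SE 0.17) and Ptprb (-0.61). Camera's adjusted p was 7.07e-11 for leukocyte and 9.11e-05 for endothelial markers, each with an adjusted p = 0.217 with an estimated correlation. Over the list alone 15 leukocyte markers rose and 6 endothelial markers fell. Leukocyte calls numbered 4, 6 and 5 without replicates 1, 2 and 4, and endothelial calls 0, 2 and 0 there and 1 without the block, where Flt1, Emcn and Ptprb had adjusted p-values of 0.152, 0.0679 and 0.187. Emcn also missed the threshold after median centring (0.068) and Ptprb with the random block (0.0518). Of 23 fibroblast and matrix markers Postn (1.67, SE 0.29, adjusted p = 0.0142), Lum (0.60, SE 0.10) and Tnc (0.47, adjusted p = 0.192 without the block and 0.0553 with the random block) rose and Col15a1 (-0.42, adjusted p = 0.0511 without the block, 0.0586 after median centring and 0.0522 without replicate 3) fell. Without replicate 3 the collagen genes Col1a1, Col1a2 and Col6a1 fell instead (adjusted p of 0.00846, 0.019 and 0.0377). In other settings 4 markers fell with array weights and 2 with the dimmest 50% left out. Without replicates 1 and 4 only 1 marker passed and without replicate 2 none, and the list did not pass (adjusted p = 0.594; over the list alone 3 rose and 1 fell).

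Of 12 Schwann cell and nerve markers only Pmp22 was called, which encodes a myelin protein that other tissues also express. It changed by -1.63 (SE 0.24, adjusted p = 0.00789), with an adjusted p = 0.0816 without the block, and the list did not pass (adjusted p = 0.476). Of 12 satellite cell markers only Chodl was called (-0.63, SE 0.14, adjusted p = 0.0372, and 0.055 without the block), Pax7 had a change of -0.09, and the list did not pass (adjusted p = 0.692). Over either list alone 1 fell, and without replicate 1 neither gene passed (0.0521 for Pmp22 and 0.173 for Chodl), nor did Chodl without replicates 3 and 4 (0.0597 and 0.131) or after median centring (0.0602). None of 9 adipocyte markers was called by limma over all genes or over the list alone, and 1 had an unadjusted p under 0.05. The adipocyte list passed as lower (median -0.23, adjusted p = 0.0257), with an adjusted p = 0.39 with an estimated correlation, and 0.181 and 0.0857 without replicates 2 and 3. Its pair medians were -0.07, -0.49, -0.40 and 0.03, and its median was -0.11 without replicate 2 and -0.37 without replicate 4. None of 12 smooth muscle and pericyte markers was called by limma with the block over all genes or over the list alone, 3 had an unadjusted p under 0.05, and that list did not pass (adjusted p = 0.121), though it did without replicate 1 (0.0466). Des, which is also among the satellite cell markers, was higher after quantile (adjusted p = 0.0404) and cyclic loess (0.0269) normalization, with array weights (0.0399) and without replicate 3 (0.0491). Rgs5 was lower with the mean of probe sets (0.0115), trended and robust moderation (0.0492) and the dimmest 25% or 50% left out (0.0288 and 0.0198). Of 4 measured blood markers S100a8 rose (2.87, SE 0.56) and Alas2, the erythroid enzyme of haem synthesis, fell (-0.66, SE 0.13), over the list alone too, and the list did not pass (adjusted p = 0.508). S100a8 missed the threshold without the block (0.0631) and without replicates 2 and 4 (0.0895 and 0.0666), and Alas2 without replicates 1, 2 and 4 (0.109, 0.0805 and 0.110).

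**Figure D2:**
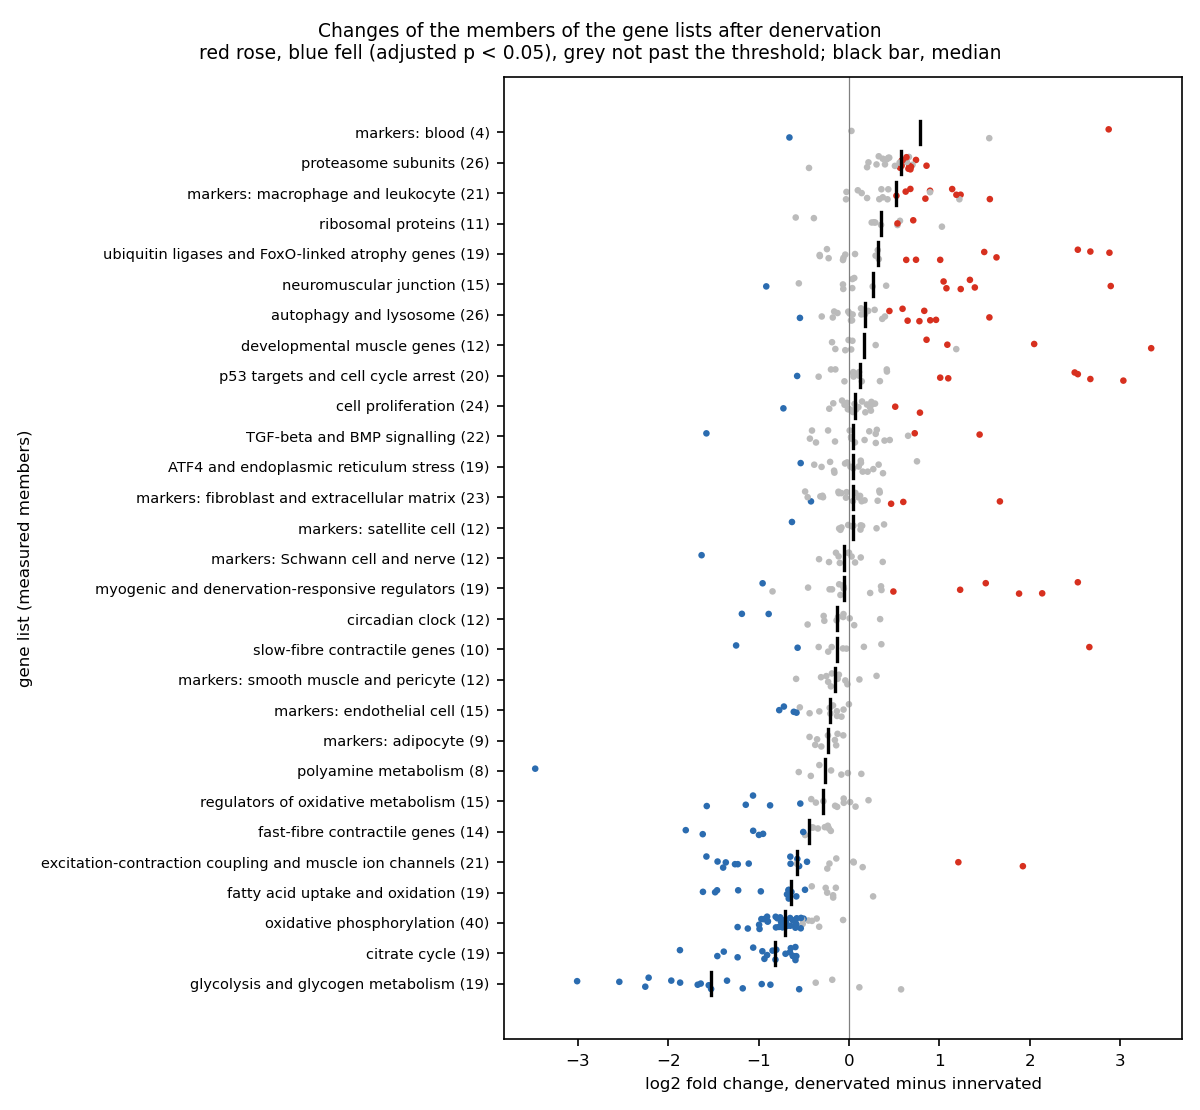
Change of each measured member (points, log2 scale, denervated minus innervated) of the 29 gene lists, named on the vertical axis with their number of measured members. Red and blue points rose or fell at an adjusted p under 0.05, and grey points did not pass. Black bars are list medians, which run from -1.52 for glycolysis and glycogen genes to 0.79 for the 4 blood markers. The blood median rests on pairs 3 and 4 (pair medians 0.06, 0.05, 2.13 and 0.88) and was 0.33 without replicate 3, where the proteasome median of 0.71 was the highest.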

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

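The tests of uniform compression and of dim against bright falling genes in this part were chosen only after the result was seen. In 152 groups of 4 arrays, 2 for each of 76 named genes, 1 array stood far from the other 3 in 10. Independent and unselected groups would give about 7.6 by chance. The named genes were in part chosen by their values and share the same arrays, so 7.6 is only a rough reference. Of the 10 groups, 7 concerned replicate 3 and 5 its denervated array. In denervated muscle, replicate 3 was lowest for Krt18 (9.74, next 10.54), Eda2r (7.13, next 9.10), Ulk2 (6.87, next 7.27), Prkaa2 (6.86, next 8.22) and Myom2 (7.10, next 8.21). In innervated muscle it was lowest for Rpl3l (9.31, next 9.59) and Runx1 (5.46, next 5.75). The others were Emb, highest in denervated replicate 4 (8.55, next 8.07), Cmbl, highest in denervated replicate 2 (5.08, next 4.78), and Tgfbr1, lowest in innervated replicate 4 (6.77, next 7.01).

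Genes that rose in the other pairs rose less in pair 3. Among 862 rising genes called without pair 3, its changes had a slope of 0.54 on the mean change of the other pairs, whereas slopes in the 137, 225 and 176 genes called without pairs 1, 2 and 4, which are other sets of genes, were 0.88, 0.96 and 1.20. Falling genes had slopes of 1.06, 0.74, 1.01 and 0.94 in pairs 1 to 4. Rising minus falling was -0.18 (SE 0.049), 0.22 (SE 0.025), -0.47 (SE 0.034) and 0.25 (SE 0.033) in pairs 1 to 4. The SEs in this paragraph are over the genes of 1 pair of arrays. Genes are not independent replicates, so these SEs do not measure the spread between arrays. The reference for pairs 1, 2 and 4 holds pair 3, so their gaps are not independent of it. A compression of all changes by 1 factor is argued against by the 781 falling genes, whose slope was 1.01 (bootstrap SE 0.022), made up of 0.70 (SE 0.039) for dim and 1.18 (SE 0.028) for bright ones. Added background as the whole cause among rising genes is argued against by dim rising genes, whose slope exceeded the 0.46 of bright ones by 0.15 (SE 0.047), while the lower slope of dim falling genes goes the way added background predicts and stays open. A level-dependent shift of the denervated replicate 3 array stays open. In genes unchanged without the pair in question, the median change in pair 3 was 0.14 among the dimmest 25% and -0.19 among the brightest 25%. It was 0.03 and 0.01 in pair 1, and went the other way in pair 2 (-0.14 and 0.13) and pair 4 (-0.08 and 0.08). The genes for pairs 1, 2 and 4 were chosen with pair 3 in the fit, which by itself can tilt them the opposite way. These values therefore cannot tell whether such a trend is particular to pair 3. With the trend on level removed the pair 3 slopes were 0.65 for rising and 0.90 for falling genes. Rising minus falling was then -0.19 (SE 0.047), 0.09 (SE 0.024), -0.25 (SE 0.031) and 0.17 (SE 0.033) in pairs 1 to 4. Not every list rose less in pair 3. The medians of leukocyte markers were 0.49, 0.39, 0.79 and 0.57 in pairs 1 to 4, and those of proliferation genes 0.08, -0.11, 0.46 and -0.07. Proteasome genes went the other way, at 0.68, 0.65, 0.05 and 0.76. Whether the cell content of pair 3 differed was not tested. No biological explanation was tested, since the design names nothing that sets these arrays apart.

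Probe sets outside the comparison also changed. Of those with several gene symbols 66 passed the threshold, 26 higher and 40 lower, and of those with no symbol 51 passed, 24 higher and 27 lower.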

How the results depend on the processing

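Cyclic loess normalization and the polyamine list without Smox were chosen after seeing the data. The count of changed genes varied more with the model and with replicates left out than with scaling. Leaving out 1 replicate number leaves fewer than 3 residual degrees of freedom, so calls lost there can come from lost power alone. Without replicate 1, oxidative phosphorylation calls went from 33 to 9, while the list median went from -0.706 to -0.703. It was 1255 (529 higher, 726 lower) with the replicate block, 800 (326 and 474) without the replicate block and 2200 (1058 and 1142) with array weights, and leaving out 1 replicate number gave 347 to 1643 (137 to 862 higher, 210 to 781 lower). Without replicate 3, 52.5% of the calls were higher, against 42.2% with all 4. The other alternatives, among them the block as a random effect (1463), quantile normalization (1294), median centring (1038) and cyclic loess (1508), stayed within 1.5 times. The count of genes changed at least 2-fold stayed between 250 and 362. The 76 named genes kept their direction in all 1061 values under 14 alternatives. Most of these values could not have turned. For a gene that moved the same way in all 4 pairs, only quantile, median and cyclic loess normalization and the mean of probe sets could reverse the direction. Of the 1061 values, 98 lost the threshold, 28 of them without replicate 1, and 5 gained it, for Myog and Pvalb. Dropping the replicate block ended 12 of 74 named calls and the call of no list.

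Of 20 lists past the threshold, 0 passed with an estimated correlation, a test with 3 residual degrees of freedom, and 3 of the 29 lists had an unadjusted p under 0.05 there. The adjusted p was then 0.217 for glycolysis, oxidative phosphorylation, citrate cycle, fatty acid, fast-fibre, polyamine, p53, leukocyte and endothelial lists, 0.281 for oxidative regulators, 0.286 for myogenic regulators, ubiquitin ligase, excitation-contraction and ribosomal lists, 0.325 for developmental genes, 0.328 for the proteasome, 0.369 for autophagy and clock genes, and 0.39 for neuromuscular junction and adipocyte lists. Fry ended the calls of the neuromuscular junction (0.0698), proteasome (0.0681), autophagy (0.0698), developmental (0.0590) and adipocyte (0.144) lists. Leaving out the dimmest 50% of genes ended those of polyamine (0.0600), clock (0.0570) and adipocyte genes (0.0852), array weights that of adipocyte genes (0.148), and omission of Smox that of polyamine genes (0.150). With 1 replicate number left out the adjusted p ranged from 0.00328 to 0.0564 for myogenic regulators, 0.00896 to 0.105 for clock genes, 0.00376 to 0.181 for adipocyte and 0.0466 to 0.295 for smooth muscle markers. Lists that passed no directional test turned direction in 6 values. These were slow-fibre genes under quantile normalization (0.995), fry (0.898) and without replicate 1 (0.392) or 4 (0.536, with 0.347 to 0.536 over the replicates), ATF4 genes without replicate 2 (0.393 to 0.984) and proliferation genes without replicate 3 (0.0654 to 0.945). Fry's mixed test, which asks whether a list's genes change in either direction, passed 27 of the 29 lists. Slow-fibre and ATF4 genes were among them (adjusted p = 0.00292 each), while proliferation genes were not (0.118). Where no value above shows why a call ended, the cause was not tested. What signal over background limits was not tested.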

Other observations

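In this part, the test of the share of muscle fibre RNA was chosen only after the result was seen. Outside the fixed lists, families of genes were formed by shared symbol stems. Members of the ankyrin repeat and SOCS box family were lower, namely Asb12 (-2.49), Asb15 (-2.09), Asb11 (-1.57), Asb4 (-0.86) and Asb5 (-0.72), 5 of 16 tested (adjusted Fisher p = 0.106). The chaperonin subunits Cct2, Cct3 and Cct4 were higher by 0.60, 0.64 and 0.52, 3 of 7 tested (adjusted p = 0.146), and the Toll-like receptor genes Tlr4, Tlr2 and Tlr6 by 1.68, 0.94 and 0.60, 3 of 12 tested (adjusted p = 0.433). Each of these genes passed limma's threshold and kept its direction under quantile, median and cyclic loess normalization, though Asb5, Cct2 and Cct3 missed the threshold after median centring (adjusted p of 0.0689, 0.0536 and 0.0626) and Tlr2 after quantile normalization (0.0505). Without the block Asb5, Cct2, Tlr2 and Tlr6 missed it (0.0609, 0.110, 0.0689 and 0.0511). Over 363 families and 2 directions 3 passed, Ndufa, Ndufb and Psmc, whose members are mostly in the fixed lists. The number of families mostly outside the lists with an adjusted Fisher p under 0.05 was 0, and 27 of them had an unadjusted p under 0.05. Other such families had an adjusted Fisher p below that of the Toll-like receptor genes. They were Cox (0.106), Map2k, Ndufaf and St3gal (0.151 each), Chchd (0.231) and Eif (0.243). Of the called members, 4 were lower and 1 higher in Cox, and 4 higher and 1 lower in Eif. In the other families named here all called members were lower.

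The calgranulin genes differed between pairs. S100a8 changed by 0.36, 3.92, 4.20 and 3.01 in pairs 1 to 4, and its partner S100a9 by -0.17, 0.30, 4.28 and 1.79 (adjusted p = 0.211).

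The fall of the energy metabolism lists was set against a lower share of muscle fibre RNA in the denervated muscle. That explanation predicts that markers of every other cell type rise alike. The leukocyte median exceeded the endothelial median by 0.81 ± 0.17 (SD of 4 pairs), with the first above 0 and the second below 0 in each pair. The fibroblast list had a median of 0.04, or -0.02 without replicate 3. If marker levels follow cell share, which was not tested, these values argue against a lower fibre share as the whole cause. A rise in leukocytes themselves stays open, and a response of the fibres to denervation is a hypothesis that the design names and that was not tested separately.

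Genes of the glycolysis and glycogen list fell further than oxidative phosphorylation genes, with a difference between list medians of -0.82 on the log2 scale. A two-sided permutation test over genes gave p = 1e-05, the smallest that 100000 permutations can give, though genes are not independent replicates. The difference was -0.53, -0.64, -0.99 and -0.73 in pairs 1 to 4, and 0.125 is the smallest two-sided exact p that 4 pairs allow. Brightness of the probe sets is argued against. With each glycolysis or glycogen gene matched to the oxidative phosphorylation gene nearest in innervated level, the median difference was -0.71 ± 0.19 (SD of 4 pairs). The replicate 3 arrays are argued against too, since pairs 1, 2 and 4 averaged -0.63. Differences in probe response between genes, and a larger response of the glycolysis and glycogen genes to denervation, were not tested and stay open. Glycolysis genes were not tested apart from glycogen genes. The pattern was found and tested on the same data.

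Whether another grouping of the arrays gives as many genes was counted by refitting. Without the block, the real split of the 8 arrays gave 800 genes and the highest of the other 34 splits 0, so 1 of 35 splits reached the real count. This count cannot exclude chance. The design takes the muscles of both legs from operated animals, so free splits ignore pairing within animals, whichever arrays share 1 animal. With the block, the real split gave 1255 genes and the highest other 0, but only 8 splits part all 4 pairs, too few for a share under 0.05, and 1 of them reached the real count.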
